A study of Mus musculus with 14 samples.

How the data were processed

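The values analysed were the log2 expression levels that the authors deposited for 14 Affymetrix arrays of pooled mouse mammary glands, made with RMA per the submitters' processing notes; no version of RMA is given in the sources used here. RMA corrects background, normalizes quantiles between arrays and summarises the probes of a probe set on the log2 scale, so weak signals are compressed and small folds are understated. The array design text names Murine U74Av2 arrays, whereas the 45101 probe sets of the deposited table are those of the Mouse Genome 430 2.0 array; gene names were therefore taken by probe set through the platform annotation supplied for that table. Of the 45037 probe sets that remained after 64 control probe sets were left out, 34945 carried 1 gene symbol, 932 several, and 9160 were unnamed here, and the named ones covered 18193 genes. Symbols were looked up again through gene identifiers in the RefSeq table of mouse assembly GRCm38.p6, which changed 0 of them, and no coordinates were taken from it. No gene was named from a probe set with several symbols or none. Scanner intensities were not used here.

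Groups were taken from the treatment named for each sample in the labels. Total RNA of 20 ug from the pooled glands of a group was labelled for each array, per the labels' protocols. The blocker doses are not given in the sources used here, and the E2 dose is not printed because its unit in the labels is in doubt. The precision is limited by the number of arrays, 2 in each of 4 groups and 1 in each of 6.

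Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment over all 45037 probe sets, adjusted p under 0.05). The 5 comparisons among vehicle, E2, acolbifene and E2+acolbifene, including the difference between the acolbifene effects with and without E2, used a fit of those 8 arrays with no other term. The 18 comparisons that involve an array without a replicate used a fit of all 14 arrays with the raw-file code as a term, in which an array without a replicate is assumed to vary like the replicated groups; comparisons of such an array with vehicle or acolbifene then pass through the 2 E2 arrays, the only group that holds both codes. Comparisons of such an array with E2 rest on E2 array 1 alone. A level called dim lay below the 40 percentile of mean level (6.65), and the size of a fold over it is not exact. A plain difference is the difference of group means without a fit. Samples with the same replicate number were not treated as pairs. Intervals are 95% intervals from the same fit.

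Gene lists were 15 lists of pathways and 13 lists of cell type markers: estrogen receptor targets, nuclear receptors, immediate-early genes, cell cycle, ribosome biogenesis, chaperones and endoplasmic reticulum stress, IGF and insulin signalling, Wnt, BMP and TGF-beta signalling, cholesterol synthesis, fatty acid and triglyceride synthesis, glucocorticoid-responsive and metallothionein genes, angiogenic and vasoactive factors, interferon response, chemokines and inflammation, and the circadian clock, and markers of milk protein secretion, luminal cells, basal and smooth muscle cells, adipocytes, brown adipocytes, skeletal muscle, endothelium, fibroblasts and matrix, macrophages, lymphocytes, erythroid cells, Schwann cells and nerve, and keratinocytes. Of their 526 genes 493 were measured, each by the probe set with the highest mean over the 14 arrays. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. With the preset correlation camera called 14 lists for E2, 13 for acolbifene, 9 for E2+acolbifene against E2, 11 for E2+acolbifene against vehicle and 14 for the difference of the acolbifene effects, 61 in all, and with an estimated correlation 0. Comparisons with 1 array per group had no list test; the list median was placed among 10000 random lists matched on mean expression.

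Genes were named by a fixed rule. For a comparison of replicated groups these were the 12 genes with the largest rise and the 12 with the largest fall among called probe sets with 1 gene symbol whose arrays did not overlap between the groups (6 and 6 for E2+acolbifene against vehicle and for the difference of the acolbifene effects). For comparisons with an array without a replicate they were the 5 and 5 largest called changes, or, where none passed, the 3 and 3 largest above the median level, named as not passing. Members of the lists, Esr1, Esr2 and Pgr could be named in every comparison, and genes named for E2 were followed through the other groups. A gene with several probe sets was named by the one with the largest change. Groups, comparisons, tests, gene lists, the naming rule and the alternatives, apart from those said below to be added, were fixed before the data were examined.

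The share of the E2 effect absent was computed on the 100 probe sets with the highest and the 100 with the lowest limma statistic for E2 array 2 against vehicle in a fit of the code R137 arrays. It is the slope through the origin of the difference between the E2 array of the same raw-file code and the array in question on the fitted E2 effect, so that vehicle gives 100% against E2 array 2 by construction. Median E2 effects on this list were 1.20 and -0.71. Overlaps of calls between comparisons that share arrays were set beside 50 draws of simulated arrays. These kept the E2 effect and had no effect in the other comparison.

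Alternatives were another quantile normalization, centring each array on its median, removing probe sets below the 40 percentile of mean level, a threshold of 1.5-fold, an intensity trend with a robust prior, the raw-file code as a term or left out, arrays of code R137 alone, a block for the replicate number, the mean of all probe sets of a gene, an estimated correlation in list tests, other gene lists for the reversal measure, and leaving out each replicated array in turn. Removing probe sets that track the skeletal muscle markers (Pearson r over 0.7 in size across the 14 arrays) and a reversal list from E2 array 1 were added after seeing the data. The steps were tested on simulated data with 200 probe sets changed among 45037. For E2 against vehicle, 6% of those changed 1.25-fold, 90% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold were called, with 12 false calls; for E2+raloxifene against E2 the shares were 0%, 46%, 98% and 100% with 11 false calls, and for raloxifene against vehicle 0%, 8%, 74% and 100% with 12. In simulated arrays without changes camera called 0 of 28 lists. The simulated probe sets varied independently of each other, so this check could not show false calls that arise from correlation between genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.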

Results

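Gene expression was measured in mammary glands of ovariectomized female C57BL/6 mice 3 h after treatment with vehicle, with 17-beta-estradiol (E2), with a blocker of estrogen receptors, or with E2 and a blocker together. Treatment was given 7 days after removal of the ovaries, the main source of circulating estrogen. The 4 blockers were fulvestrant, a steroidal antiestrogen, and the nonsteroidal ligands acolbifene (a benzopyran), raloxifene (a benzothiophene) and tamoxifen (a triphenylethylene). Vehicle, E2, acolbifene and E2+acolbifene had 2 arrays each, and fulvestrant, raloxifene, tamoxifen and their combinations with E2 had 1 array each, 14 arrays in 10 groups. Glands of the mice of a group, 8 by the labels, were pooled, and nothing in the labels says whether the 2 arrays of a group came from separate pools. All p-values therefore measure only the spread between arrays, which may be technical, and the number of arrays limits the precision.

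The array medians lay between 7.16 and 7.23 on the log2 scale. In the vehicle pair 111 probe sets were over 1.5-fold apart, in the acolbifene pair 153, in the E2+acolbifene pair 75 and in the E2 pair 310. The median difference of 18 skeletal muscle markers was -1.24 log2 for E2 array 1 minus E2 array 2. The raw-file names carried a code, R136 or R137, whose meaning the labels do not state. E2 array 1 and the 6 arrays without a replicate carried R136, and the other 7 arrays carried R137. Hybridization control spikes averaged 9.86 to 10.04 on the E2 arrays and the arrays without a replicate, and 10.23 to 10.41 on the vehicle, acolbifene and E2+acolbifene arrays. Both E2 arrays thus differed in these spikes from vehicle and from E2+acolbifene, although E2 array 2 shares their raw-file code. A technical difference tied to this split cannot be told apart from the E2 effect, and the code as a model term does not remove it. The 3' minus 5' difference of the Actb control was 0.24 to 0.28 in vehicle and 0.41 to 0.43 after E2.

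The comparison of E2 with vehicle asked which genes estradiol moved within 3 h. Krt4, a keratin of stratified epithelia, was 12.3-fold higher after E2 (log2 change 3.62 ± 0.15, SE, 2 arrays per group, limma adjusted p = 8.76e-07). Pgr, the progesterone receptor and a classical target of the estrogen receptor, was 6.79-fold higher (2.76 ± 0.16, adjusted p = 5.72e-06). Acot1, an acyl-CoA thioesterase, rose 6.51-fold and F3, the tissue factor that starts blood coagulation, 4.83-fold. Mmd2 rose by 2.75 and Mfsd4a by 2.08 on the log2 scale from dim vehicle levels (6.44 and 5.82), with 1.90 at a brighter probe set of Mmd2 and 1.95 and 0.41 (adjusted p = 0.0396) at those of Mfsd4a. Ccn1, a matricellular protein of the immediate-early response, rose 4.02-fold, Smim38 3.72-fold, Aqp5, a water channel of gland epithelia, 3.40-fold and Mad2l1, a component of the spindle checkpoint, 3.07-fold. Mtmr7, a phosphoinositide phosphatase, fell (log2 change -1.83 ± 0.23, adjusted p = 0.00139) at a probe set that was dim after E2 (5.71), with -0.67 at a brighter one (adjusted p = 0.00832). Foxa1, a transcription factor that opens chromatin for the estrogen receptor, fell by 1.52 on the log2 scale (adjusted p = 0.00118), Tmprss2, a serine protease of epithelia, by 1.33, Lratd1 by 1.32 and Slc7a2, an amino acid transporter, by 1.20. Prol1 fell by 1.15, Dixdc1 by 1.14, the growth factor receptor Fgfr2 by 1.07, the desaturase Scd2 by 1.00, the clock output factor Dbp by 1.00, Acss2, which makes acetyl-CoA, by 1.00 and Smim3 by 0.96. Brighter probe sets of Acss2 gave -0.48 (adjusted p = 0.015) and -0.30 (adjusted p = 0.09). Prol1 was dim after E2 (4.48). Some of these genes stood apart from vehicle by over 0.25 log2 on all 12 other arrays, whatever the treatment: Mmd2 and Smim38 lay above both vehicle arrays on each, and Prol1, Dixdc1 and Dbp below. By a smaller margin Krt4, Ccn1 and Aqp5 did so above and Scd2, Tmprss2 and Slc7a2 below.

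Across all probe sets, limma called 1685 of 45037 for E2 at an adjusted p under 0.05, 933 higher and 752 lower, which covered 1202 genes, and 523 of these probe sets changed at least 1.5-fold. Myh1 and Myh2, heavy chains of fast muscle myosin, also passed (log2 change 3.71 ± 0.35 and 1.93 ± 0.31). The muscle list as a whole had a median of -0.62 on E2 array 1 and 0.50 on E2 array 2 against vehicle. The count was 430 without vehicle array 1, 712 without vehicle array 2, 941 without E2 array 2 and 479 without E2 array 1, which is also the count with the raw-file code in the model, with 426 probe sets shared, and 2747 with an intensity trend. Of the genes named here Myh2 alone lost its call in any alternative fit (adjusted p = 0.0726 without vehicle array 1 and 0.0812 with an intensity trend). The probe sets of Pgr differed in size, the other 2 giving 0.52 (adjusted p = 0.04) and 0.17 (adjusted p = 0.426). Log2 changes of the receptors themselves were -0.23, 0.05 and -0.20 at the Esr1 probe sets (adjusted p = 0.213, 0.872 and 0.265) and 0.01 for Esr2 (adjusted p = 0.98).

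**Figure D1:**
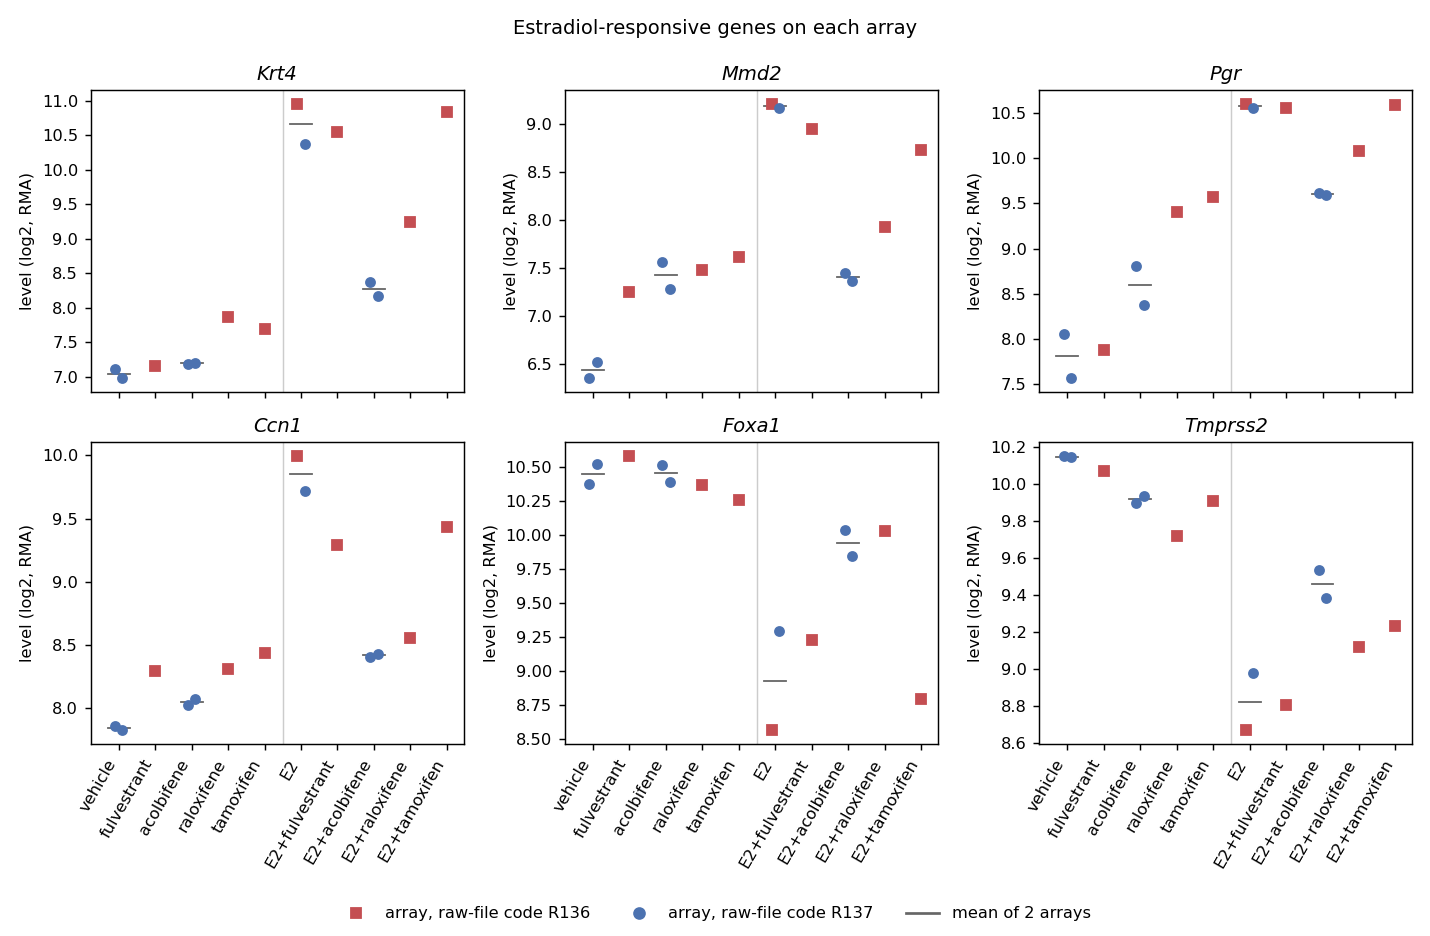
Levels (log2, RMA) of Krt4, Mmd2, Pgr, Ccn1, Foxa1 and Tmprss2 on each of the 14 arrays by group, with red squares for arrays of raw-file code R136, blue circles for code R137 and grey lines for means of 2 arrays. Krt4 lay at 7.12 and 6.97 in vehicle, 10.96 and 10.38 after E2, 8.37 and 8.17 after E2+acolbifene, 10.55 after E2+fulvestrant and 9.24 after E2+raloxifene.

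Immediate-early genes, which respond to growth signals without new protein synthesis, rose as a group after E2. Among 26 measured members 13 rose and 0 fell over all genes (18 and 1 adjusted over the list alone), among them Gadd45g (1.57), Ccn2 (1.20), Gadd45a (1.20), Junb (1.02), Egr1 (0.52), Fos (0.51) and Myc (0.48). The list test with limma's camera gave adjusted p = 2.12e-15 with the preset correlation and adjusted p = 0.0883 with an estimated correlation. Of 18 glucocorticoid-responsive and metallothionein genes, 13 rose and 0 fell (15 and 0 adjusted over the list alone). The largest of these were the metal-binding Mt2 (1.40), the cell cycle inhibitor Cdkn1a (1.03), Pdk4 (1.03), which restrains glucose oxidation, and the glucocorticoid receptor co-chaperone Fkbp5 (0.81). That list gave adjusted p = 4.18e-19, and adjusted p = 0.0883 with an estimated correlation. In 10 of its 18 members the other 12 arrays, whatever the treatment, all lay by any margin to the same side of both vehicle arrays, against 6.76% of all genes. Known estrogen receptor targets went both ways: 8 of 24 rose, Inhbb (0.84) and Sgk1 (0.73) besides Pgr, and 2 fell, Cish (-0.61) and Wnt4 (-0.55), with 9 and 2 adjusted over the list alone. The target list was called upward at adjusted p = 0.000351, and had adjusted p = 0.16 with an estimated correlation. In ribosome biogenesis 2 of 24 rose, Rrs1 (0.73) and Ddx21 (0.56), with 5 adjusted over the list alone (adjusted p = 0.000195, and adjusted p = 0.23 with an estimated correlation). Of 20 angiogenic and vasoactive factors 4 rose, Thbs1 (1.29), Hmox1 (1.19), Hif1a (0.59) and Adm (0.54), with 6 up and 2 down adjusted over the list alone (adjusted p = 0.00301, and adjusted p = 0.124 with an estimated correlation). Thbs1, Hmox1 and Hif1a, like Ccn2 of the immediate-early list, were above both vehicle arrays by over 0.25 log2 on all 12 other arrays.

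Enzymes of cholesterol synthesis were lower after E2 than in vehicle. Of 16 measured, 5 were lower and 0 higher (9 adjusted over the list alone): squalene epoxidase Sqle (-0.93), farnesyl diphosphate synthase Fdps (-0.77), Cyp51 (-0.68), Sc5d (-0.59) and Idi1 (-0.50). The list had adjusted p = 8.95e-07, and adjusted p = 0.0883 with an estimated correlation. Its median was below vehicle on all 12 other arrays, whatever the treatment (-0.15 to -0.51), and Sqle and Sc5d lay below both vehicle arrays by over 0.25 log2 on each of them. Genes of fatty acid and triglyceride synthesis were called downward too, with 4 of 19 lower, Scd2, Fads2 (-0.50), Mlxipl (-0.48) and Fads1 (-0.41), and 12 adjusted over the list alone (adjusted p = 1.4e-06, and adjusted p = 0.318 with an estimated correlation). The list probe set of Scd2 gave -0.53, against -1.0 and -0.75 at its other 2. Among cell type markers, the basal keratins Krt14 (0.65) and Krt5 (0.48) and the basal transcription factor Trp63 (0.64) rose. The list of basal and smooth muscle markers was called upward with these 3 of 14 higher and 6 adjusted over the list alone (adjusted p = 4.57e-07, and adjusted p = 0.0883 with an estimated correlation). Milk protein genes followed with 4 of 11 higher, Ltf (0.50), Csn3 (0.47), Lalba (0.47) and Btn1a1 (0.39), and 4 adjusted over the list alone (adjusted p = 0.00899, and adjusted p = 0.124 with an estimated correlation). Macrophage markers were called downward with 2 of 16 lower, Cd68 (-0.60) and Msr1 (-0.45), and 1 up and 8 down adjusted over the list alone (adjusted p = 9.98e-05, and adjusted p = 0.0883 with an estimated correlation). Lymphocyte markers were called downward with 2 of 17 lower, Cd79b (-0.46) and Ighm (-0.45), and 7 adjusted over the list alone (adjusted p = 0.000186, and adjusted p = 0.0883 with an estimated correlation). On all 12 other arrays, whatever the treatment, the basal list median was above vehicle and the lymphocyte list median below it. With raloxifene alone these medians were 0.30 and -0.34. Milk protein medians were 0.10 and 0.04 on the E2 arrays. With fulvestrant, raloxifene and tamoxifen alone they were 0.16, 0.20 and 0.11, and with acolbifene alone 0.002 and -0.018.

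Acolbifene without E2 was set against vehicle to ask what the blocker did in the absence of estradiol. Serpinb2, an inhibitor of plasminogen activators, was 4.48-fold higher (log2 change 2.16 ± 0.13, adjusted p = 0.000135). C1qtnf3, a secreted adipokine, was higher by 2.0 and Arg1, the arginase of alternatively activated macrophages, by 1.63 on the log2 scale. The neutrophil chemokines Cxcl2 (1.48), Cxcl5 (1.24) and Cxcl3 (1.07) rose together with Fam107a (1.36), the collagen Col12a1 (1.17), thrombospondin Thbs1 (1.13), Mup10 (1.11) and Fkbp5 (1.10). The sizes are not exact for genes dim in vehicle, which were C1qtnf3 (4.71), Arg1 (6.04), Cxcl2 (6.17), Cxcl5 (6.41), Cxcl3 (4.73), Fam107a (5.29) and Myh1 (4.89). Myh1 was higher (2.89 ± 0.35, adjusted p = 0.00541), while the muscle list median was -0.04 and -0.09 on the 2 acolbifene arrays. The genes that fell most were Prol1 (-1.09), the immunoglobulin genes Ighm (-1.05) and Igkv9-120 (-0.85), Dbp (-0.99), Csnk2a1 (-0.85), Mtarc1 (-0.80), Tomm7 (-0.77), Ncan (-0.73), Npr3 (-0.73), Krtdap (-0.72), Mmd (-0.72) and Fam25c (-0.68). Prol1 (4.54) and Krtdap (6.02) were dim after acolbifene. By over 0.25 log2, Fam107a, Thbs1, Fkbp5 and Myh1 lay above both vehicle arrays on all 12 other arrays, and Prol1, Dbp, Csnk2a1 and Ncan below. The other 10 probe sets of Ighm ranged from -0.25 to 0.06. Brighter probe sets did not pass for Csnk2a1 (0.08 and 0.25), Mmd (0.11 and 0.07), Tomm7 (-0.41), Npr3 (-0.51) and Col12a1 (0.44), and that of Fam107a gave 0.48 (adjusted p = 0.0484). Pgr had a log2 change of 0.78 (adjusted p = 0.0546).

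In total limma called 269 probe sets for acolbifene, 183 higher and 86 lower (119 and 96 after another quantile normalization), in 202 genes. The count was 27 without vehicle array 1 or without acolbifene array 1, 51 without vehicle array 2 and 64 without acolbifene array 2. It was 706 with dim probe sets removed and 1469 with an intensity trend, under which Myh1 had adjusted p = 0.0868. Serpinb2, C1qtnf3, Arg1, Fam107a, Col12a1, Thbs1, Fkbp5, Cxcl3 and Prol1 were called in each alternative that was run. Glucocorticoid-responsive genes rose here too, 9 of 18 with 14 adjusted over the list alone, among them Fkbp5, Zbtb16 (0.97), Cdkn1a (0.83), Ddit4 (0.77) and Tsc22d3 (0.67). The list had adjusted p = 2.42e-17, and adjusted p = 0.101 with an estimated correlation. Fibroblast and matrix genes were called upward with 2 of 17 higher, Timp1 (0.69) and Lox (0.53), and 14 adjusted over the list alone (adjusted p = 1.21e-09, and adjusted p = 0.208 with an estimated correlation). Macrophage markers had 2 of 16 higher, Cd14 (0.57) and Cd163 (0.51), and 10 adjusted over the list alone (adjusted p = 2.36e-05, and adjusted p = 0.101 with an estimated correlation). Genes of chemokines and inflammation had 3 of 26 higher and Ccl5 lower (-0.48), with 11 and 1 adjusted over the list alone (adjusted p = 0.00033, and adjusted p = 0.158 with an estimated correlation). Cholesterol synthesis genes were lower with 2 of 16, Fdps (-0.65) and Sqle (-0.51), and 4 adjusted over the list alone (adjusted p = 1.15e-06, and adjusted p = 0.101 with an estimated correlation). Lists of keratinocyte (2 of 10 lower, adjusted p = 0.000264), brown adipocyte (1 of 10 lower, adjusted p = 8.51e-05) and lymphocyte markers (0 of 17, with 7 adjusted over the list alone, adjusted p = 0.000216) were called downward. Chaperones (1 of 21 higher, adjusted p = 3.64e-06), estrogen receptor targets (2 of 24, adjusted p = 0.000609), immediate-early genes (2 of 26, adjusted p = 0.003), ribosome biogenesis (0 of 24, adjusted p = 0.003) and angiogenic factors (2 of 20, adjusted p = 0.0116) were called upward. With an estimated correlation these 8 lists had adjusted p = 0.101, 0.306, 0.101, 0.226, 0.208, 0.388, 0.371 and 0.208.

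Acolbifene given with E2 was compared with E2 alone to ask how far it prevented the estradiol response. Krt4 was 5.26-fold lower in the combination (log2 change -2.40 ± 0.15, adjusted p = 0.000124), Mmd2 3.42-fold (-1.78 ± 0.11, adjusted p = 0.000124), F3 2.74-fold, Ccn1 2.70-fold and Mad2l1 2.60-fold. Greb1, an estrogen-induced cofactor of the receptor, fell by 1.23, Mfsd4a by 1.37, Cped1 by 1.21, Cox10 by 1.20, the pentraxin Ptx3 by 1.12, Ankra2 by 1.12 and the protease Adamts1 by 1.12. Brighter probe sets of several of these did not pass: Cox10 (0.09 and 0.08), Ankra2 (0.19), Cped1 (-0.03), Greb1 (0.12) and Mfsd4a (0.07), whose other brighter probe set gave -1.29 (adjusted p = 0.00302). The named probe sets of these 5 genes were dim in the combination (5.75 to 6.52), and a brighter one of Mmd2 gave -1.32 (adjusted p = 0.000254). Foxa1 was 2.02-fold higher (1.02 ± 0.18, adjusted p = 0.0206), together with Mtmr7 (1.08), the arginase Arg2 (0.86) and Rcn1 (0.82). The brighter probe set of Rcn1 gave -0.29 (adjusted p = 0.0939) and a dimmer one of Arg2 -0.24 (adjusted p = 0.224). The remaining genes named as higher encode proteins of skeletal muscle: Ttn (1.09), Apobec2 (1.06), Pygm (1.06), Myl2 (0.96), Trdn (0.93), Actn2 (0.91), Casq1 (0.88) and Myom2 (0.88). Brighter probe sets of Ttn (0.55) and Apobec2 (0.26) did not pass, while that of Mtmr7 (0.54) did. Those of Myom2 gave 0.46 (adjusted p = 0.025), 0.28 (adjusted p = 0.404) and 0.23 (adjusted p = 0.597). Mtmr7, Arg2, Rcn1, Apobec2, Myl2, Trdn and Myom2 were dim after E2 (5.47 to 6.38), so their sizes are not exact. The muscle list median against vehicle was 0.72 and 0.67 on the E2+acolbifene arrays, beside -0.62 and 0.50 on the E2 arrays.

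The comparison called 1649 probe sets, 736 higher and 913 lower in the combination, in 1256 genes (275 and 759 after another quantile normalization, 427 and 2102 with arrays centred on the median). It fell to 284 with the raw-file code in the model, which equals the count without E2 array 1, and 220 probe sets were shared. The count was 240 without E2 array 2, 223 without E2+acolbifene array 1, 116 without E2+acolbifene array 2 and 3108 with an intensity trend. With the code the calls of Foxa1 (0.65, adjusted p = 0.0542), Mtmr7 (0.60, adjusted p = 0.0762), Ttn (0.56, adjusted p = 0.0667), Apobec2, Pygm, Myl2, Casq1 and Myom2 were lost. Immediate-early genes fell, 13 of 26 with 16 adjusted over the list alone, among them Gadd45a (-0.96), Junb (-0.87), Fosl2 (-0.86), Gadd45g (-0.83), Egr1 (-0.76) and Fos (-0.63). The list had adjusted p = 9e-11, and adjusted p = 0.438 with an estimated correlation. Estrogen receptor targets had 5 of 24 lower, Pgr (-0.97) and Inhbb (-0.68) among them, and 2 up and 9 down adjusted over the list alone (adjusted p = 0.0177, and adjusted p = 0.438 with an estimated correlation). Dimmer probe sets of Pgr gave -0.25 (limma adjusted p = 0.236) and 0.14 (adjusted p = 0.446). Ribosome biogenesis had 4 of 24 lower, with Rrs1 (-0.78) and Nop58 (-0.64), and 10 adjusted over the list alone (adjusted p = 7.04e-06, and adjusted p = 0.438 with an estimated correlation). In the glucocorticoid list 4 of 18 fell, Saa3 (-0.85), Mt2 (-0.80), Cdkn1a (-0.47) and Cebpb (-0.39), and Zbtb16 rose (0.44), with 1 up and 8 down adjusted over the list alone (adjusted p = 0.00812, and adjusted p = 0.438 with an estimated correlation). The muscle list was called upward (adjusted p = 7.73e-07, and adjusted p = 0.457 with an estimated correlation) with Casq1 alone of 18 members past the threshold over all genes and 12 adjusted over the list alone. Chaperones (1 of 21 lower, adjusted p = 0.0121), chemokines (4 of 26, adjusted p = 0.0177), endothelial markers (0 of 14, adjusted p = 0.0228) and cell cycle genes (1 of 25, adjusted p = 0.0246) were called downward, and had adjusted p = 0.457, 0.438, 0.438 and 0.438 with an estimated correlation.

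Of the probe sets called for E2, 523 were also called in E2+acolbifene against E2, and 517 of these had moved back toward vehicle, 398 raised by E2 and 119 lowered by it. Independent lists of these sizes would share 18.9 and 12.3. Simulated arrays that kept the E2 effect but had E2+acolbifene at the E2 level shared 0.16 on average and at most 2 in 50 draws. A comparison simulated without an effect yields few calls, so this count cannot show how much the shared arrays add. Both comparisons use the E2 arrays, so part of the excess may come from the shared arrays; the covariance of the changes was -0.0248, against -0.00573 in the simulation. Acolbifene alone shared 110 probe sets in the same direction with E2 among 112 called in both, 80 higher and 30 lower. Independent lists would share 3.79 and 1.44. The simulation, here with acolbifene at the vehicle level, gave 0.28 on average and at most 4, with the same limit. The vehicle arrays are shared there, and the covariance was 0.0151 beside 0.00579 in the simulation.

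E2+acolbifene against vehicle asked what remained of the estradiol response under the blocker. Pgr stayed 3.48-fold above vehicle (log2 change 1.80 ± 0.16, adjusted p = 0.00064), Acot1 3.36-fold (1.75 ± 0.13, adjusted p = 0.000231) and Krt4 was higher by 1.23 (adjusted p = 0.00564). Dimmer probe sets of Pgr gave 0.27 (limma adjusted p = 0.247) and 0.31 (adjusted p = 0.168). Muscle genes were higher as well, Myh1 by 4.38, Myh2 by 2.72, and Mb and Actn2 by 1.69 each. The vehicle levels of Myh1 (4.89), Myh2 (5.25) and Actn2 (6.06) lay below the 40 percentile of mean level (6.65), as did Ttc25 (6.27) in the combination, so the sizes of these changes are not exact. The muscle list was called at adjusted p = 1.44e-10 with 3 of 18 higher and 10 adjusted over the list alone (adjusted p = 0.354 with an estimated correlation). Lower were Ighm (-1.50), Igkv9-120 (-1.10), the mucosal defence gene Dmbt1 (-1.10), Slfn4 (-1.05), Tmprss2 (-0.97) and Ttc25 (-0.96). Other probe sets of Ighm ran from -0.70 to 0.30, with -0.70 and -0.52 at the brightest, and those of Igkv9-120 gave -0.09 and -0.07. Enzymes of cholesterol synthesis were lower with 8 of 16, among them Cyp51 (-0.80), Sqle (-0.79), Idi1 (-0.75) and Fdps (-0.69), and 12 adjusted over the list alone (adjusted p = 5.9e-11, and adjusted p = 0.096 with an estimated correlation). Glucocorticoid-responsive genes were higher with 9 of 18, led by Zbtb16 (1.12) and Ddit4 (0.82), and 14 up and 1 down adjusted over the list alone (adjusted p = 5.9e-11, and adjusted p = 0.106 with an estimated correlation). Zbtb16, Sqle and Myh1 stood apart from vehicle on all 12 other arrays, including those without E2. For compounds without E2, glucocorticoid list medians against vehicle ran from 0.21 (fulvestrant) to 0.65 (acolbifene array 1). The cholesterol list medians of these compounds ran from -0.45 (fulvestrant) to -0.18 (tamoxifen). For these genes and lists, a remaining estradiol response cannot be told apart from a shift shared by all arrays other than vehicle. Lymphocyte markers were called downward with 1 of 17 lower and 15 adjusted over the list alone (adjusted p = 1.49e-08, and adjusted p = 0.096 with an estimated correlation). Interferon genes (1 of 19 lower, adjusted p = 2.5e-09), fatty acid and triglyceride synthesis (2 of 19, adjusted p = 1.12e-08), macrophage (1 of 16, adjusted p = 0.000186) and endothelial markers (1 of 14, adjusted p = 0.000186) were called downward. Keratinocyte markers (2 of 10 higher, adjusted p = 0.00111), basal and smooth muscle markers (0 of 14, adjusted p = 0.00399) and milk protein genes (0 of 11, adjusted p = 0.0389) were called upward. With an estimated correlation these 7 lists had adjusted p = 0.227, 0.302, 0.106, 0.227, 0.114, 0.227 and 0.227. The lymphocyte and basal list medians lay to the same side of vehicle on all 12 other arrays, so the limit of a shared shift holds for them too. Milk protein medians were 0.16 and 0.11 on the E2+acolbifene arrays, beside 0.16, 0.20 and 0.11 with fulvestrant, raloxifene and tamoxifen alone.

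Against vehicle 377 probe sets were called for E2+acolbifene, 204 higher and 173 lower, in 274 genes (167 and 346 with arrays centred on the median). The count was 65 without vehicle array 1, 41 without vehicle array 2, 34 without E2+acolbifene array 1, 39 without E2+acolbifene array 2, 630 with dim probe sets removed and 1736 with an intensity trend. All 205 probe sets called here and for E2 had the same direction, 106 higher and 99 lower. Independent lists would share 4.23 and 2.89. The simulation, with the vehicle arrays shared and E2+acolbifene at the vehicle level, gave 0.18 on average and at most 2. Such a simulation yields few calls for E2+acolbifene, so it cannot show how much the shared arrays add. The covariance was 0.0172 beside 0.00575 in the simulation, and part of the overlap may come from the shared vehicle arrays. The shared calls include Myh1, Smim38 and Prol1, which stood apart from vehicle on all other arrays, whatever the treatment.

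The acolbifene effect with E2 was then set against its effect without E2, a difference that contains the vehicle arrays. Mmd2 had a difference of -2.77 (adjusted p = 5.05e-05; 0.99 with acolbifene alone) at a probe set dim in vehicle (6.44). A brighter one gave -1.60 (adjusted p = 0.000484), with 0.28 for acolbifene alone (adjusted p = 0.209). Serpinb2 rose alone by 2.16 while its change in the presence of E2 was -0.06 (difference -2.22, adjusted p = 0.000423). In the glucocorticoid list 11 of 18 members had a lower acolbifene effect under E2, with 16 adjusted over the list alone (adjusted p = 1.83e-12, and adjusted p = 0.229 with an estimated correlation). In 10 of those 18 genes all 12 other arrays lay to the same side of both vehicle arrays. In the immediate-early list 16 of 26 members had a lower acolbifene effect under E2, with 2 up and 18 down adjusted over the list alone (adjusted p = 1.52e-09, and adjusted p = 0.229 with an estimated correlation). Chemokine genes had 9 of 26 lower (adjusted p = 0.00077, and adjusted p = 0.229 with an estimated correlation). The difference was called at 2011 probe sets, 697 higher and 1314 lower (495 and 2658 with arrays centred on the median). The count was 238 without vehicle array 1, 1039 without vehicle array 2, 1113 without E2 array 1 or with the raw-file code, 387 without E2 array 2 and 298 without acolbifene array 1. It was 894 without E2+acolbifene array 1, 186 without E2+acolbifene array 2 and 4218 with an intensity trend.

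All 4 blockers were then compared in how much of the estradiol effect they removed. The measure was the share of the E2 effect absent from an array over the 100 probe sets with the highest and the 100 with the lowest limma statistic for E2 array 2 against vehicle. Each array was set against the E2 array of the same raw-file code. With E2, this share was 41.1% for acolbifene (40.2% and 42.1% on its arrays), 36.3% for raloxifene, 20.5% for fulvestrant and 7.95% for tamoxifen, while E2 array 1 against E2 array 2 gave 8.50%. The order of acolbifene and raloxifene turned against the mean of the E2 arrays (36.9% and 40.6%), the list from E2 array 1 gave 32.2% for acolbifene, and all called probe sets gave 14.3% for tamoxifen. Genes raised by E2 were moved back by 43.7%, 42.8%, 21.3% and 10.5% in the same order, and genes lowered by it by 31.4%, 11.8%, 17.4% and -1.91%. Without E2, where a compound that leaves these genes at the vehicle level would score near 100%, the share was 65.3% for acolbifene, 56.2% for raloxifene, 54.6% for fulvestrant and 53.5% for tamoxifen. Simulated arrays with no reversal gave 5.22% on average for acolbifene (2.07% to 7.14% in 50 draws), which shares the E2 array with the gene list, and 0.16% for tamoxifen (-4.20% to 2.93%). Simulated compounds at the vehicle level gave 97.2% for acolbifene and 92.0% to 92.3% for the others. The compounds alone scored below this, so part of the difference between E2 and vehicle on these genes was also present without E2. The cause of that was not tested. A share with E2 is therefore to be read beside that of the same compound alone, and not against 100% only. The groups without a replicate have no error of their own here. Hybridization spikes averaged 10.23 to 10.41 on the acolbifene arrays with and without E2, and 10.04 on their reference, E2 array 2. The other blocker arrays (9.86 to 10.04) lay near their reference, E2 array 1 (10.01). Only the acolbifene shares thus compare arrays across the split in these spikes. A technical difference tied to it cannot be told apart from the place of acolbifene in the order.

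**Figure D2:**
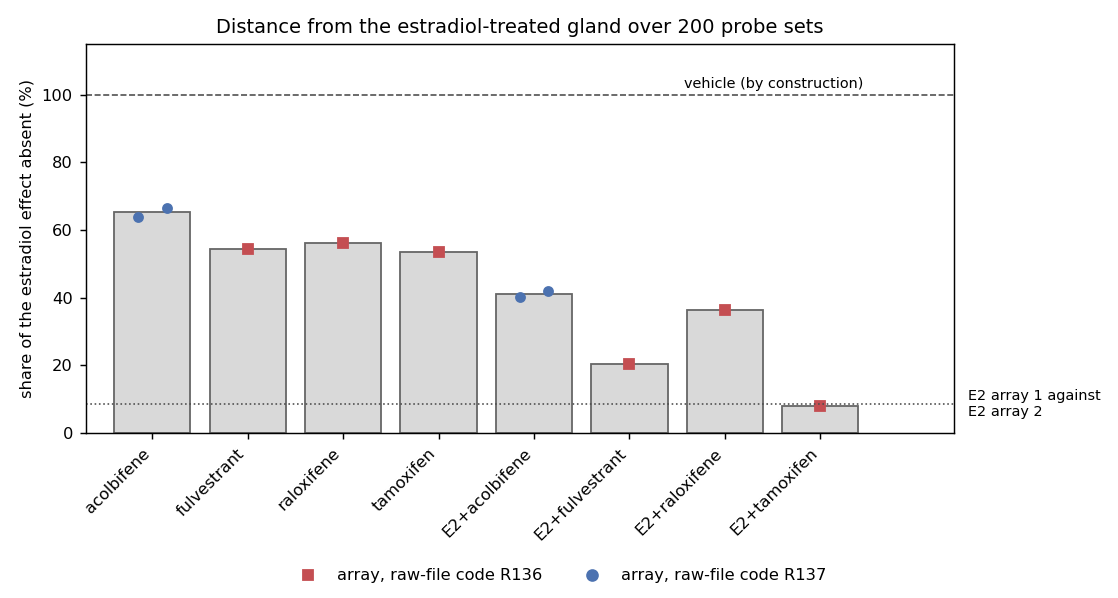
Share of the estradiol effect absent (%, vertical axis) over 200 probe sets for each blocker alone and with E2, as bars with a point for each array (red squares code R136, blue circles code R137), a dashed line for vehicle at 100% by construction and a dotted line for E2 array 1 against E2 array 2. With E2 the bars stand at 7.95% for tamoxifen, 20.5% for fulvestrant, 36.3% for raloxifene and 41.1% for acolbifene (40.6% and 36.9% for the last pair against the mean of the E2 arrays; 5.22% for acolbifene in simulated arrays with no reversal), and the compounds alone lie between 53.5% and 65.3%. Only the acolbifene bars compare arrays across the split in hybridization spikes.

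For blockers with 1 array the comparison with E2 has no replicate check of its own and rests on the spread in the replicated groups. With the raw-file code as a term the fitted value is the difference from E2 array 1 alone. On the E2+raloxifene array Krt4 (-1.72 ± 0.14, adjusted p = 0.00455), Ccn1 (-1.44) and Mfsd4a (-1.50) were lower than on E2 array 1, and against E2 array 2 they gave -1.14, -1.16 and -1.0. Foxa1 was higher by 1.47 ± 0.14 (adjusted p = 0.00781), and by 0.74 against E2 array 2. Serpinb2 (1.84), Slfn4, a gene of myeloid cells (1.75), Cxcl5 (1.61) and the interleukin receptor antagonist Il1rn (1.38) were higher too, with 2.18, 0.96, 1.03 and 1.05 against E2 array 2. Myh1 (-1.58), Phf21b (-1.32), Gadd45g (-1.26) and the muscle actin Acta1 (-0.95) were lower on that array, whose muscle list median against vehicle was -1.47. E2+fulvestrant differed from E2 in Lor, the loricrin of the cornified skin layer (2.40 ± 0.20, adjusted p = 0.0069), Krt77 (1.45), Myh4 (1.56) and Myh1 (-1.87), and its median of keratinocyte markers against vehicle was 0.86. Against E2 array 2, which was higher in muscle genes, Myh4 differed by -0.18, Myh1 by -3.47, Lor by 2.04 and Krt77 by 1.19. E2+tamoxifen differed in Nrsn2 (1.20, adjusted p = 0.0449), Prkra (1.11, adjusted p = 0.0487) and Mt2 (-1.13, adjusted p = 0.0487), the last by -0.42 against E2 array 2. Sizes are not exact for Nrsn2 (5.78), Prkra (4.71), Lor (5.61) and Cxcl5 (6.40), dim in E2, nor for Myh1 and Phf21b, dim with E2+raloxifene (6.07 and 5.75), with Myh1 dim with E2+fulvestrant as well (5.94). In the fit of all 14 arrays with the raw-file code, limma called 43 probe sets for E2+raloxifene (15 higher, 28 lower), 10 for E2+fulvestrant (4 and 6) and 6 for E2+tamoxifen (2 and 4, or 0 and 4 with arrays centred on the median). The count for E2+raloxifene was 28 without either E2+acolbifene array, that for E2+fulvestrant 6 without either vehicle or either E2+acolbifene array, and that for E2+tamoxifen 0 without any 1 of the vehicle, acolbifene or E2+acolbifene arrays. Without the raw-file code E2+tamoxifen had 1453 and E2+raloxifene 85, and with dim probe sets removed E2+raloxifene had 94 and E2+fulvestrant 18.

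List medians in these comparisons were placed among 10000 random lists of like expression. Their genes were drawn singly and so lack the correlation that members of a list can have, and a position outside them is not a test. The glucocorticoid list lay at -0.22 for E2+fulvestrant, -0.23 for E2+raloxifene and -0.29 for E2+tamoxifen against E2, each below every random list. The immediate-early list lay at -0.08 for E2+fulvestrant (percentile 0.45), -0.15 for E2+raloxifene (percentile 0.01) and -0.14 for E2+tamoxifen (percentile 23.5). Ribosome biogenesis lay at -0.09 for E2+fulvestrant (percentile 0.18), -0.19 for E2+raloxifene and -0.24 for E2+tamoxifen. Macrophage (0.35), fibroblast (0.30), interferon (0.21) and chemokine genes (0.20) lay above every random list for E2+raloxifene. For E2+fulvestrant interferon genes (-0.15) lay below every random list, and macrophage (-0.01), fibroblast (-0.04) and chemokine genes (-0.03) at percentiles 40.2, 10.7 and 6.99. Cell type markers also differed between that array and E2 array 1. Lymphocyte markers (-0.20) lay below every random list, and skeletal muscle (0.70), keratinocyte (0.43) and brown adipocyte markers (0.34) above every one. Against vehicle the muscle median was -0.04 on E2+fulvestrant, -0.62 on E2 array 1 and 0.50 on E2 array 2. The direction for muscle thus depends on the E2 array used. Muscle (0.31) and brown adipocyte markers (0.15) also lay above every random list for E2+tamoxifen, and muscle (-0.74) below every one for E2+raloxifene. For E2+tamoxifen the 4 lists in the first order gave -0.10, -0.14, -0.05 and -0.08, at percentiles 89.0, 48.4, 97.6 and 31.4.

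Fulvestrant, raloxifene and tamoxifen without E2 were compared with vehicle in the same fit. Values of Pgr below are those of its brightest probe set. Its dimmer ones gave -0.37 and 0.15 with fulvestrant, -0.31 and 0.09 with raloxifene, and -0.18 and 0.02 with tamoxifen. Pgr was 0.02 log2 from vehicle with fulvestrant (95% interval -0.69 to 0.74), 1.55 with raloxifene (0.84 to 2.27, adjusted p = 0.452) and 1.72 with tamoxifen (1.01 to 2.43, adjusted p = 0.299). Fulvestrant gave 69 calls, 63 higher and 6 lower, of which Myh1 (5.86), Myh2 (3.82), Myot (2.48), Apobec2 (2.40), Tnni2 (2.28) and Ckm (2.16) belong to skeletal muscle, and C1qtnf3 (2.85) and Cxcl5 (1.76) do not. Mvd, an enzyme of cholesterol synthesis, was lower (-1.11, adjusted p = 0.0424), and the median of the cholesterol list was -0.45 for fulvestrant and -0.34 for raloxifene, below every random list, and -0.17 for tamoxifen (percentile 0.76). Raloxifene gave 4 calls, 2 probe sets of Myh1 (3.38 and 2.62) and 2 probe sets unnamed here (2.37 and -1.82). Tamoxifen gave 5, of which Myh1 accounted for 2 (4.64 and 3.77), Myh2 (2.64) and Mybpc1 (1.88) for 2, and a probe set unnamed here (-2.32) for the last. These unnamed probe sets were chosen after their values were seen. Without the raw-file code the counts were 153 for fulvestrant, 90 for raloxifene and 74 for tamoxifen. All these differences pass through the E2 pair, whose muscle genes differed by a median of -1.24. Plain differences of the fulvestrant array from the vehicle mean were 4.26 for Myh1, 2.41 for Myh2, 1.20 for Myot, 1.94 for Apobec2, 2.15 for C1qtnf3 and -0.62 for Mvd. Those of Myh1 were 1.79 for raloxifene and 3.04 for tamoxifen, and for tamoxifen Myh2 gave 1.23 and Mybpc1 1.21. Vehicle levels were dim for C1qtnf3, Mybpc1 and all the muscle genes for which a plain difference is given. Directly against the vehicle mean the muscle list medians were 0.75 for fulvestrant, -0.26 for raloxifene and -0.24 for tamoxifen.

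**Figure D3:**
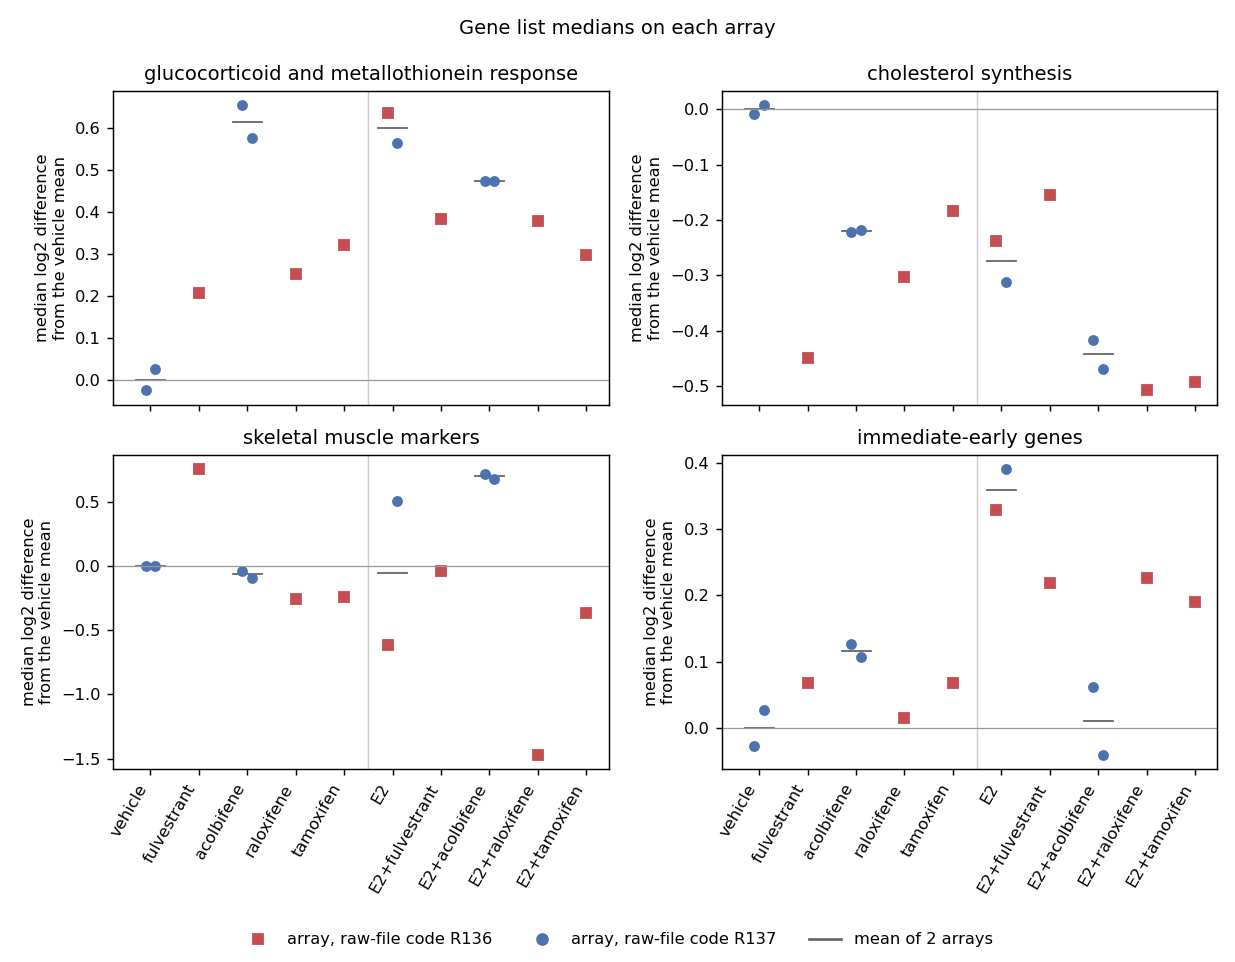
Median difference from the vehicle mean (log2, vertical axis) on each array by group for the glucocorticoid and metallothionein, cholesterol synthesis, skeletal muscle and immediate-early lists, with red squares for code R136, blue circles for code R137 and grey dashes for means of 2 arrays. Glucocorticoid medians were above 0 on all 12 treated arrays, from 0.21 with fulvestrant to 0.65 on an acolbifene array, and cholesterol medians were below 0 on all 12, from -0.15 with E2+fulvestrant to -0.51 with E2+raloxifene.

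The compounds were compared with each other at the same time point; their doses are not given in the sources used here, so the values stand side by side without matching of dose. Each arm apart from acolbifene was 1 array of pooled glands, so a call here compares arrays with a spread taken from other groups. With E2 present, the benzothiophene raloxifene and the triphenylethylene tamoxifen arrays differed at 46 probe sets, 22 higher and 24 lower with raloxifene (24 in total without either vehicle array, 20 without the raw-file code and 91 with dim probe sets removed). Serpinb2 (2.50, adjusted p = 0.000768), Cxcl5 (2.37), the acute-phase protein Saa3 (1.68), Dmkn (1.61), Slfn4 (1.60) and Foxa1 (1.23, interval 0.91 to 1.56) were higher with raloxifene. Krt4 (-1.61, interval -1.93 to -1.29, adjusted p = 0.00478), Greb1 (-1.40), Ccn1 (-0.88, interval -1.15 to -0.61), Myh1 (-2.22), Tnnc2 (-1.42) and Mybpc2 (-1.29) were lower. The muscle list medians of these arrays against vehicle were -1.47 and -0.37. Serpinb2 and Cxcl5 were dim with E2+tamoxifen (6.37 and 5.36) and Myh1 and Greb1 with E2+raloxifene (6.24 and 5.92). Without E2, 1 probe set unnamed here passed between them (-1.73, adjusted p = 0.02), 1729 were under an unadjusted p of 0.05, and without either vehicle or either acolbifene array limma called 0. Serpinb2 (1.18, adjusted p = 0.176) and Myh1 (-1.25, adjusted p = 0.115) did not pass.

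Raloxifene differed from the steroidal fulvestrant at 29 probe sets with E2 (8 higher, 21 lower; 0 in total without the raw-file code and 55 with dim probe sets removed), with Slfn4 (1.71), Serpinb2 (1.57), Cthrc1 (1.36), Cxcl5 (1.34) and Mmp12 (1.16) higher. Krt4 (-1.32, interval -1.64 to -1.0, adjusted p = 0.0105), Lor (-1.78), Myh4 (-1.89), Tnnc2 (-1.83), Tnni2 (-1.75) and Pvalb (-1.71) were lower, with muscle list medians of -1.47 and -0.04 against vehicle. Without E2 they differed at 15, with Smim38 higher (1.31) and Myh1 (-2.47), Myh2 (-2.12), Apobec2 (-1.73), Ighm (-1.30) and Mylpf (-1.16) lower. Pgr differed by 1.53 (interval 0.99 to 2.07, adjusted p = 0.139). The count without E2 was 4 without either vehicle or either acolbifene array and 7 without either E2+acolbifene array, 3 without the raw-file code and 26 with dim probe sets removed. Tamoxifen differed from fulvestrant at 13 probe sets with E2 (6 without the raw-file code), where Myh1 (2.53) was higher and the skin genes Lor (-2.89), Tchh (-2.53), Krt77 (-1.87), Krt10 (-1.80) and Krt25 (-1.70) were lower. Krt4 differed by 0.29 (interval -0.03 to 0.61, adjusted p = 0.533). Without E2 they differed at 21 (12 without either vehicle array, 0 without either acolbifene array, 10 without either E2+acolbifene array, 5 without the raw-file code and 43 with dim probe sets removed). Smim38 (1.26) was higher, C1qtnf3 (-1.90), Apobec2 (-1.42), Myh1 (-1.30), Cthrc1 (-1.24) and Serpina1b (-1.22) were lower, and Pgr differed by 1.70 (interval 1.16 to 2.24, adjusted p = 0.0611). The lower array was dim for Smim38, C1qtnf3, Apobec2, Myh2, Cxcl5, Lor, Tchh and Krt25 in these comparisons (4.0 to 6.51), and for Myh1 with E2+fulvestrant, so sizes are not exact. Keratinocyte marker medians against vehicle were 0.86 on E2+fulvestrant, 0.26 on E2+raloxifene and 0.16 on E2+tamoxifen. No array apart from E2+fulvestrant exceeded 0.27, so the skin gene differences rest on that array. Without E2, dimmer probe sets of Pgr gave 0.06 and -0.05 for raloxifene against fulvestrant, and 0.19 and -0.13 for tamoxifen.

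Acolbifene, on 2 arrays of the other raw-file code, was compared with the remaining blockers through the E2 pair, so the muscle gap of that pair enters each fitted value. With E2 it differed from raloxifene at 5 probe sets: Slfn4 (-2.42), Cxcl5 (-2.32) and Il1rn (-1.78) were lower with acolbifene, as was a probe set unnamed here (-2.94), and another unnamed one (1.60) was higher. Plain group differences of these 3 genes were -1.63, -1.74 and -1.45. For Krt4 the E2 pair also differed, with levels of 10.96 and 10.38, and this gap enters its fitted values below. Krt4 lay at 8.37 and 8.17 with E2+acolbifene and at 9.24 with E2+raloxifene, a larger gap than the fitted one. Its plain differences were -2.28 against E2+fulvestrant and -2.57 against E2+tamoxifen. The count was 3 without any 1 of the vehicle, acolbifene or E2+acolbifene arrays. Krt4 differed by -0.39 between those combinations (interval -0.81 to 0.03, adjusted p = 0.745); a p that misses the threshold does not show that they act alike. Against fulvestrant with E2 it differed at 2 unnamed probe sets (1.78 and -1.74), with 1 higher and 3 lower when arrays were centred on the median and 0 without any 1 of those arrays. In that comparison Krt4 (-1.71, interval -2.13 to -1.29, adjusted p = 0.0635) and Mmd2 (-1.50, interval -1.98 to -1.02, adjusted p = 0.211) did not pass, nor did Myh4 (-1.86, adjusted p = 0.056), whose plain difference was -0.12. Against tamoxifen with E2 limma called 0 probe sets, with 1578 under an unadjusted p of 0.05, and Krt4 differed by -2.0 (interval -2.42 to -1.58, adjusted p = 0.0654) and Dmkn by 1.60 (adjusted p = 0.103). Without E2, acolbifene and fulvestrant differed at 44 probe sets (29 without either acolbifene array). Serpinb2 (1.75) and Ppp1r3b (1.52) were higher, and Myh1 (-2.96), Tnnc2 (-2.55), Tnni2 (-2.54), Myh4 (-2.45) and Mylpf (-2.40) were lower. Plain differences of these muscle genes were -1.37, -1.02, -1.12, -0.71 and -1.16. Acolbifene and tamoxifen alone differed at Serpinb2 (2.72, adjusted p = 0.0172), a call that was lost without either acolbifene array. Serpinb2 was dim with tamoxifen (6.49) and Cxcl5 with E2+acolbifene (5.98). Against raloxifene alone limma called 0, with 2357 under an unadjusted p of 0.05. In that comparison Serpinb2 was at 1.53 (adjusted p = 0.25, plain difference 1.20), and the plain differences of Myh4 and Tnnc2 were -0.04 and 0.01, beside fitted values of -1.78 and -1.52 (adjusted p = 0.235 for each). Without the raw-file code the counts with E2 were 49, 73 and 59 against fulvestrant, raloxifene and tamoxifen, and those without E2 were 221, 287 and 178.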

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

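The test behind this part, of the difference between the acolbifene effects with and without E2, was fixed before the data were examined, and no explanation was weighed for it. The difference passed the limma threshold at 2011 probe sets. It contains the vehicle arrays, from which Mmd2, Myh1 and Prol1 stood apart on all 12 other arrays (Prol1 at 5.62 in vehicle and 4.44 to 4.83 on the others). Krt4 differed by -2.55 on the log2 scale (0.15, adjusted p = 0.679, without E2 and -2.40 with it). Mmd2 differed by -2.77 (0.99 and -1.78) at a probe set dim in vehicle, and by -1.60 (0.28, adjusted p = 0.209, and -1.32) at a brighter one. Myh1 differed by -2.23 (2.89 and 0.66, the latter at adjusted p = 0.261), Serpinb2 by -2.22 and C1qtnf3 by -2.20 (2.00 and -0.19, the latter at adjusted p = 0.558). Mup10, a major urinary protein, went opposite ways, 1.11 without E2 (adjusted p = 0.0175) and -0.96 with it (adjusted p = 0.02), a difference of -2.07. Among positive differences, Ngp, a neutrophil granule protein, had 1.49 (adjusted p = 0.0228), although neither of its own effects passed (-0.81, adjusted p = 0.1, and 0.68, adjusted p = 0.0814). Prol1 had 1.40 (-1.09 and 0.32, the latter at adjusted p = 0.119), Spaca3 1.39 (-0.72 and 0.68) and Lor 1.39 (-0.69, adjusted p = 0.0701, and 0.70, adjusted p = 0.0352; its other probe sets 0.21 and 0.32). Ranbp3 had 1.28 (-0.61 and 0.68; its brighter probe sets -0.06 and 0.05) and the muscle enzyme Pygm 1.24 (-0.18 and 1.06). Prol1, Lor and Ranbp3 were dim in E2 and C1qtnf3 in E2+acolbifene, so these sizes are not exact. The calls of Pygm, Ranbp3, Spaca3, Myh1 and Ngp were lost in several alternative fits.

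Lists called for this difference besides those of the report were ribosome biogenesis (4 of 24 lower, adjusted p = 4.57e-06, and adjusted p = 0.231 with an estimated correlation), chaperones (5 of 21 lower, adjusted p = 1.33e-05, and adjusted p = 0.258 with an estimated correlation), fibroblast and matrix genes (3 of 17 lower, adjusted p = 1.95e-05, and adjusted p = 0.359 with an estimated correlation) and estrogen receptor targets (7 of 24 lower, adjusted p = 0.000628, and adjusted p = 0.231 with an estimated correlation). Called downward as well were macrophage markers (2 of 16, adjusted p = 0.00847), cell cycle (1 of 25, adjusted p = 0.0107), interferon (1 of 19, adjusted p = 0.0186) and angiogenic genes (4 of 20, adjusted p = 0.0257), and upward keratinocyte (2 of 10, adjusted p = 0.0101) and brown adipocyte markers (1 of 10, adjusted p = 0.0219). With an estimated correlation these 6 lists had adjusted p = 0.229, 0.258, 0.51, 0.258, 0.229 and 0.482. The muscle list was called upward (adjusted p = 0.00243, and adjusted p = 0.566 with an estimated correlation) with a median of 0.93 and a mean of 0.55, although its 1 member past the threshold over all genes had a negative difference.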

How the results depend on the processing

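The alternatives of this part were chosen before the data were examined, except the removal of probe sets that track muscle and the reversal list from E2 array 1, which were chosen after seeing the data. In the alternatives that changed scale, filter or model, 1 named value reversed, that of Tnnc2 for acolbifene against raloxifene, to 0.011 (adjusted p = 0.992) without the raw-file code. Of the values compared, 193 kept direction and call with arrays centred on the median (4 changed a call), 91 after another quantile normalization (5 lost), 88 with the intensity trend (8 lost), 150 with dim probe sets removed (6 gained), 90 without muscle-tracking probe sets (0 lost) and 144 with the raw-file code as a term (13 lost), while 49 kept it without the code (42 lost, 9 gained). Where no construction is named the cause was not tested. The 2 arrays of a group limit every count, and dim probe sets lie near background, where RMA compresses changes.

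With the raw-file code as a term, and equally with the arrays of code R137 alone, the counts were 479 for E2, 284 for E2+acolbifene against E2 and 1113 for the difference of the acolbifene effects; both settings set E2 array 1 aside. Another quantile normalization gave 1034 and 1114 for the last pair of results, and centring gave 2529 and 3153, and 4 for E2+acolbifene against E2+fulvestrant. The intensity trend with a robust prior gave 2747 for E2, 1469 for acolbifene, 3108 for E2+acolbifene against E2, 1736 for E2+acolbifene against vehicle and 4218 for the difference. A threshold of 1.5-fold left 523, 132, 360 and 190 for the first 4. List tests with an estimated correlation called 0 of 61, and the mean of all probe sets of a gene 60 of 61, the brown adipocyte list of the difference having adjusted p = 0.0659.

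The replicate numbers did not pair the samples: deviations of same-numbered arrays correlated over probe sets at 0.117, -0.0796, -0.123, -0.0803, -0.117 and 0.0908. With a replicate block the count was 1002 for E2+acolbifene against E2 and 1193 for the difference of the acolbifene effects.

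Removing dim probe sets, which leaves fewer to adjust over, gave 706 for acolbifene, 630 for E2+acolbifene against vehicle, 18 for E2+fulvestrant against E2, 94 for E2+raloxifene against E2, 13 each for raloxifene and tamoxifen against vehicle, 91 for E2+raloxifene against E2+tamoxifen and 2 for the same compounds alone. It gave 55 for E2+raloxifene against E2+fulvestrant, 26 and 43 for raloxifene and tamoxifen against fulvestrant, and 5, 8 and 3 for E2+acolbifene against E2+fulvestrant, E2+raloxifene and E2+tamoxifen, with 10 for acolbifene against tamoxifen. Without the raw-file code the counts were 85 for E2+raloxifene and 1453 for E2+tamoxifen against E2, 153, 90 and 74 for fulvestrant, raloxifene and tamoxifen against vehicle, 20 for E2+raloxifene against E2+tamoxifen and 5 for them alone. They were 0 for E2+raloxifene and 6 for E2+tamoxifen against E2+fulvestrant, and 3 and 5 without E2. Those of acolbifene were 49, 73 and 59 with E2 against fulvestrant, raloxifene and tamoxifen, and 221, 287 and 178 without E2.

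Leaving out each replicated array in turn gave 430 to 1615 for E2, 27 to 194 for acolbifene, 116 to 1481 for E2+acolbifene against E2, 34 to 409 for E2+acolbifene against vehicle and 186 to 1444 for the difference. It gave 6 to 9 for E2+fulvestrant, 28 to 36 for E2+raloxifene and 0 for E2+tamoxifen against E2, 24 to 37 for E2+raloxifene against E2+tamoxifen, 0 to 1 for them alone, 4 to 7 and 0 to 12 for raloxifene and tamoxifen against fulvestrant. For acolbifene it gave 0 and 3 with E2 against fulvestrant and raloxifene, 29 to 38 against fulvestrant alone and 0 to 1 against tamoxifen alone. A lone array left in a group was assumed to vary like the other groups.

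The share of the E2 effect absent, on all called probe sets, was 47.4% for E2+acolbifene, 18.8% for E2+fulvestrant, 37.8% for E2+raloxifene, 14.3% for E2+tamoxifen and 53.9% for raloxifene alone. Against the mean of the E2 arrays it was 36.9%, 24.8%, 40.6% and 12.2%, and for the compounds alone 61.1%, 58.8%, 60.5% and 57.7%, in the order acolbifene, fulvestrant, raloxifene, tamoxifen. With 50 probe sets per direction E2+tamoxifen had 6.12%. The list from E2 array 1 gave 32.2% for E2+acolbifene and 51.6% for acolbifene alone, and without muscle-tracking probe sets fulvestrant alone had 57.8% and tamoxifen alone 54.9%. Without a vehicle array the range was 34.4% to 35.1% for E2+raloxifene, 8.47% to 10.8% for E2+tamoxifen, and 61.4% to 63.0% (acolbifene), 50.9% to 53.0% (fulvestrant), 51.7% to 54.2% (raloxifene) and 48.7% to 52.1% (tamoxifen) for compounds alone.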

Other observations

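The tests of the 3 patterns weighed in this part were chosen after the result was seen, except the simulation of array noise. Clock genes differed from vehicle in both directions after E2. Of 16 measured, 6 were higher, the repressor Nfil3 (0.91), Npas2 (0.85), Per1 (0.53), Clock (0.43), Cry1 (0.40) and Arntl (0.40), and 3 lower, Dbp (-0.94), Bhlhe40 (-0.62) and Per3 (-0.44), with 6 up and 6 down adjusted over the list alone. In 8 of the 16 all 12 other arrays, whatever the treatment, lay to the same side of both vehicle arrays, Dbp among them. The list test was not called (adjusted p = 0.373), and its median was -0.02 with a mean of 0.04. Luminal markers went both ways as well: the tight junction gene Cldn4 (0.91), the stem cell antigen Prom1 (0.86) and Krt7 (0.45) rose, and Foxa1 (-1.52), the luminal transcription factor Gata3 (-0.84) and Cldn3 (-0.55) fell, out of 17 (adjusted p = 0.609, median 0.03, mean -0.02). With acolbifene present, Foxa1 (1.02), Gata3 (0.73) and Cldn3 (0.67) were higher than with E2 alone and Prom1 (-0.49) was lower. In the adipocyte list Pck1 rose (0.60) and the glucose transporter Slc2a4 (-0.56) and the hormone leptin, Lep (-0.88), fell, out of 15 (adjusted p = 0.373).

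Among the remaining lists for E2 against vehicle, interferon genes were called downward with 0 of 19 past the threshold over all genes and 2 adjusted over the list alone (adjusted p = 2.59e-05, and adjusted p = 0.318 with an estimated correlation). Keratinocyte markers were called upward with 0 of 10 and 2 adjusted over the list alone (adjusted p = 0.00301, and adjusted p = 0.111 with an estimated correlation), and Schwann cell markers downward with Pmp22 (-0.36) lower of 5 and 3 adjusted over the list alone (adjusted p = 0.0393, and adjusted p = 0.194 with an estimated correlation). Chemokines and inflammation were not called (adjusted p = 0.0823), although Socs3 (1.36), Ccl7 (0.66) and Nfkbia (0.37) rose, nor were chaperones (adjusted p = 0.0886), with the heat shock genes Hspa1a (0.66) and Hspa1b (0.65) higher. The list test gave adjusted p = 0.3 for skeletal muscle (median -0.15, mean 0.29), 0.373 for cell cycle, 0.502 for nuclear receptors, 0.916 for IGF and insulin signalling, 0.329 for Wnt, BMP and TGF-beta signalling, 0.122 for brown adipocytes, 0.198 for endothelium, 0.771 for fibroblasts and matrix and 0.886 for erythroid cells.

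The first pattern is that the vehicle arrays stood apart from the other 12 at 80 probe sets, with 44 higher and 36 lower on all treated arrays by at least 0.25 log2; Fkbp5, Zbtb16, Mt2, Pdk4 and Ccn2 were higher, and Sqle, Mvd, Sc5d, Prol1 and Dbp were lower. Standing apart was not particular to vehicle: by the same measure the acolbifene pair lay above all 12 others at 67 probe sets and below at 38, the E2 pair at 38 and 9 and the E2+acolbifene pair at 6 and 3. The pattern was defined against all 12 other arrays, which include the other 5 arrays of the vehicle code. A raw-file code that vehicle shares with those 5 does not by itself set vehicle apart from them. The lowest median of the glucocorticoid list on them, 0.472, is part of the pattern and no separate test of the code. Array noise was simulated in 100 sets of arrays, in which at most 1 probe set stood apart. There vehicle was set at the mean of the other 12 arrays, which kept their own differences, so it had little room to stand apart. Noise was drawn separately for each array, and a deviation shared by both vehicle arrays was not simulated. The simulation therefore cannot decide on array noise. A difference in time of day or handling of the vehicle pool may contribute and stays open: 8 of 16 clock list members lay to the same side of both vehicle arrays on all other arrays, against 6.76% of all genes, but so did 10 of 18 glucocorticoid list members. A response to injected ligand, which the design names for all other groups, is likewise open and was not tested.

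The second pattern is in skeletal muscle genes. All 18 muscle markers were lower on E2 array 1 than on E2 array 2, Acta1 at 10.91 against 12.03 and Ckm at 9.75 against 11.18, which is consistent with differing amounts of muscle in the tissue used; 15 of the 18 lay above the median level in vehicle and 0 belong to another list. The raw-file code as the cause stays open. Of the other arrays of the E2 array 1 code, the fulvestrant array alone lay above vehicle, with a muscle median of 0.752. The rest lay below, from -1.47 to -0.04, so a case against the code would rest on 1 array. Myh1 was above both vehicle arrays on all 12 other arrays, but the amount of muscle as the whole cause of that is argued against by the muscle markers other than Myh1 and Myh2, whose highest median on the acolbifene arrays was -0.0506. Myh1 was not alone among muscle genes. Mybpc1 also lay above both vehicle arrays on all 12, and acolbifene against vehicle gave 1.43 for Myh2 (limma adjusted p = 0.0691) and 0.84 for Mb (adjusted p = 0.0657). What raised Myh1 stays open, and no biological explanation was tested.

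The third pattern is that much of the estradiol response was kept on the E2+fulvestrant and E2+tamoxifen arrays. Their shares of the E2 effect absent were 20.5% and 7.95%, beside 54.6% and 53.5% for fulvestrant and tamoxifen alone. An array of E2 alone under a wrong label could give this pattern: E2+fulvestrant differed from E2 array 1 by over 1.5-fold at 133 probe sets and E2+tamoxifen at 685, where the E2 pair differed at 310 and the closest replicate pair at 75. Over 2-fold the order was different: 22 for E2+fulvestrant and 21 for E2+tamoxifen, beside 35 in the E2 pair and 0 to 1 in the other pairs. The SD of log2 values over all probe sets was smallest on the E2+tamoxifen array (1.88, beside 1.96 on E2 array 1 and 1.95 on E2+fulvestrant). An array-wide difference in scale may therefore add to its 685, which was not tested. Against a wrong label on E2+fulvestrant runs its 20.5% share of the E2 effect absent, beside 8.50% between the E2 arrays and -3.68% to 2.93% in simulated arrays with no reversal, while E2+tamoxifen had 7.95%. For both arrays a wrong label cannot be told apart from a blocker that did not reach its full effect within 3 h, because each group has 1 array and the spread of that share between arrays of E2 alone rests on 1 pair. Incomplete blockade by dose or time was not tested and stays open.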
